A study of Rattus norvegicus with 9 samples.

How the data were processed

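Gastrocnemius muscle from male rats aged 8 weeks was profiled by sequencing of messenger RNA on a BGISEQ-500, from 1 µg of Trizol-extracted RNA per library. There were 9 libraries in 3 groups of 3: SHAM (a sham operation), DN (sciatic nerve injury without stimulation) and DN-SM (sciatic nerve injury with daily electrical stimulation through surface electrodes for 4 weeks from surgery, at 25 V, 1 mA, 2 Hz and a pulse width of 300 ms). Animals of SHAM and DN were also anaesthetised and fitted with electrodes, without current. The labels do not state when SHAM and DN muscle was collected, the time of day of collection, the kind of nerve injury, or whether a replicate number means the same thing in different groups.

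The deposited files give, for each library, an expected count and an FPKM per gene. The expected count is, per the file headers, the estimate that RSEM writes, with no normalization by the authors, and genes at 0 are not listed. The FPKM values, per the file headers, were scaled by the authors to effective transcript length and to the number of fragments in the library. Per the submitters' processing notes, GATK, HISAT2 and RSEM were used with the rat genome build rn6; the notes give no versions, settings or order. The files give no positions, and no coordinates were used here. Over all libraries 13752 gene IDs occurred, of which 11151 were listed in all 9; genes missing from a file were set to 0. Symbols came from a RefSeq table: 13649 IDs matched by gene ID and 7 by transcript accession, and 96 stayed without a symbol.

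Totals of expected counts ranged from 7926445 to 8893843 per library, so a difference in a gene with few counts could be missed. A gene absent from a file has no floor given here, since the files list only values above 0.

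Expected counts were rounded and tested with the quasi-likelihood F test (two-sided, robust) of edgeR 4.0.16 in R 4.3.3. Libraries were scaled with TMM factors, and genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 10129 genes. The 9 libraries entered 1 fit with the group as the only term, and the comparisons DN against SHAM, DN-SM against DN and DN-SM against SHAM were contrasts of it. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, with a threshold of 0.05. They measure the spread between these samples; the labels do not say that each library came from a separate animal. Changes are log2 fold changes from this fit with its standard error (SE), and levels are the authors' FPKM as mean ± SD with n = 3.

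There were 35 gene lists, written for denervated muscle, its metabolism, and the other cell types of the tissue. Of 593 members written, 563 matched a measured gene. Lists with at least 5 tested members, 33 in all, were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01 and adjusted over the lists of a comparison. The same test with an estimated correlation, and fry, were alternatives. Members are counted as higher or lower over all genes tested and, where stated, adjusted over the list alone. No list was moved in any comparison of all 9 libraries with an estimated correlation.

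Named genes followed a rule. In each comparison it took the 8 largest rises and the 8 largest falls among genes past the threshold, with a mean FPKM of at least 5 in the higher group and with no overlap between the groups' libraries; chance gives such a separation in 10% of genes at 3 against 3. When none passed, it took the 4 genes with the smallest p. It also took up to 3 members of each list with the smallest adjusted p, and always Chrna1, Chrng, Myog, Fbxo32, Trim63, Myh4, Myh7, Ppargc1a and Col1a1. Not every list member so taken is printed. Groups, tests, lists, the rule and the alternatives below were fixed before the data were examined, except where an addition is stated.

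The alternatives were RLE and upper-quartile factors, the Wald test of DESeq2 1.42.0, no filter, a filter at a CPM of 1 in 3 libraries, a fit of only the 2 groups compared, the replicate number as a block, limma with trend on log2 FPKM with a pseudocount of 1 or 0.1 and with or without a filter at an FPKM of 1 in 3 libraries, limma-voom with sample weights, library sizes without the 20 most abundant genes, and leaving out each library in turn. Added after the data were seen were further variants of the fit of DN and DN-SM alone, including removal of each library's loess trend with transcript length (span 0.5), the list tests in fits of 2 groups, those with an estimated correlation with each library left out, and the naming rule applied to the fit of DN and DN-SM alone.

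Overlaps between comparisons that share a group were set beside 20 simulated data sets drawn from the fitted means and dispersions, with DN-SM equal to DN or with no difference between groups. The test was also tested on simulated data in which 200 genes were changed, 50 at each fold. For DN-SM against DN it recovered 11 of 50 genes at 1.5-fold, 34 at 2-fold, 46 at 3-fold and 49 at 4-fold, and called 9 of 9929 unchanged genes. For DN against SHAM the counts were 8, 27, 46 and 45 of 50, with 10 unchanged genes called, and for DN-SM against SHAM 8, 27, 36 and 48, with 4 called. Every group was drawn there with the same dispersion for each gene. The real common dispersion, as a coefficient of variation, was 0.219 within SHAM, 0.143 within DN and 0.142 within DN-SM. The simulation thus could not show how many unchanged genes are called when SHAM varies more. In simulated data with 1 list shifted, camera called that list and 0 of 19 others. Genes were drawn independently there, so this could not show how the preset correlation of 0.01 performs on correlated genes. In the real data the estimated correlation was 0.841 for the slow-fibre list in DN against SHAM. No pair of libraries was a duplicate: the chi-squared per degree of freedom between libraries was at least 7.22.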

Results

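Gene expression was measured in the gastrocnemius, a calf muscle supplied by the sciatic nerve, in 3 groups of 3 libraries: SHAM (sham operation), DN (sciatic nerve injury) and DN-SM (sciatic nerve injury with daily surface electrical stimulation). Total expected counts were 7926445, 8717293 and 8893843 in SHAM replicates 1 to 3. They were 8644286, 8402522 and 8518451 in DN, and 8597996, 8622582 and 7946227 in DN-SM. Between 12232 and 12484 genes were listed per library. Acta1, the actin of skeletal muscle thin filaments, was the most abundant gene, with 9.63% to 13.12% of the counts.

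The first principal component held 30.8% of the variance and the second 19%. On the first, the DN libraries lay at 22.15 to 24.53 and the DN-SM libraries at -11.51 to -8.45, while the SHAM libraries spread from -39.09 (replicate 2) to 9.73 (replicate 3). The median SD of log2 CPM (counts scaled to library size) within a group was 0.251 in SHAM, 0.187 in DN and 0.171 in DN-SM. SHAM replicates 2 and 3 thus stood apart from each other on this axis, and each comparison was also run without each of them.

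**Figure D1:**
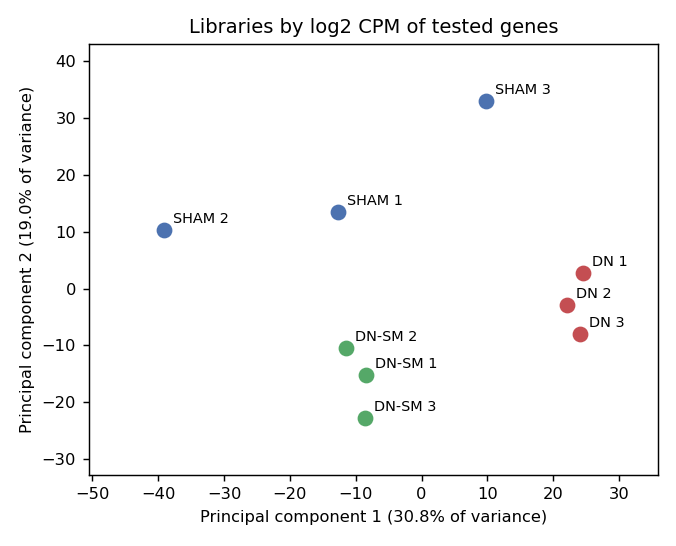
Positions of the 9 libraries on the first principal component (horizontal, 30.8% of the variance) and the second (vertical, 19%) of log2 CPM of the tested genes, coloured by group. The DN libraries lie together at 22.15 to 24.53 on the first component, and the SHAM libraries range from -39.09 to 9.73.

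The comparison of DN with SHAM addressed what sciatic nerve injury did to the muscle. Several genes known to respond to loss of the nerve were higher in DN. Cdkn1a, an inhibitor of the cell cycle, rose from 8.57 ± 1.91 to 82.6 ± 43.3 FPKM (SD, n = 3; log2 fold change 3.18, SE 0.396, edgeR adjusted p = 0.00825). Ankrd1, a stretch-responsive protein of the sarcomere, rose by 2.39 on the log2 scale (adjusted p = 0.0136), and Myog, a transcription factor of muscle differentiation, rose from 18.5 ± 4.57 to 35.0 ± 4.48 FPKM (0.86, adjusted p = 0.018). Fbxo32, the muscle ubiquitin ligase also called atrogin-1, was lower, at 4.33 ± 1.74 FPKM in DN and 10.9 ± 3.20 in SHAM (log2 fold change -1.40, adjusted p = 0.0232). Trim63, the ligase MuRF1, had a log2 fold change of -0.37 that did not pass (adjusted p = 0.173).

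Of 10129 genes tested in DN against SHAM, 432 changed, 260 higher and 172 lower in DN. The change was at least 2-fold in 148 of them, and 2256 genes had an unadjusted p under 0.05. By the naming rule, which 334 genes met, the largest rises were in Apod, a lipid-binding secreted protein (gene ID 25239; 4.22 ± 1.02 FPKM in SHAM and 46.1 ± 14.9 in DN; log2 fold change 3.38, adjusted p = 0.00812), and in Cdkn1a, Ciart, Tmem158, Cst7, Myh3, Ankrd1 and Thrsp. Ciart, a repressor of the circadian clock, rose by 3.15 (adjusted p = 0.00901), and Tmem158, a membrane protein, by 2.65 (0.00825). Cst7, a cysteine protease inhibitor of leukocytes, rose by 2.43 (0.0285), and Thrsp, a regulator of fat synthesis, by 2.34 (0.0206). The largest falls were in Ltb, Bmal1, Cib2, Unc5a, Chac1, Fkbp5, Aqp4 and Dnajc21. Ltb, the cytokine lymphotoxin beta, fell from 8.32 ± 1.71 to 1.52 ± 0.342 FPKM (log2 fold change -2.51, adjusted p = 0.00232), and Bmal1, an activator of the circadian clock, from 6.94 ± 1.43 to 1.29 ± 0.362 (-2.49, 0.00232). Fkbp5, a co-chaperone of steroid receptors, had a log2 fold change of -1.78 (0.00235), and Aqp4, a water channel of fast fibres, of -1.71 (0.00812). The others were at -2.27 for Cib2, a calcium-binding protein (0.026), -1.92 for Unc5a, a netrin receptor (0.00823), -1.89 for Chac1, which degrades glutathione (0.0462), and -1.70 for Dnajc21, a ribosome-related co-chaperone (0.0114).

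In DN against SHAM the count of changed genes was 247 without SHAM replicate 1 (123 higher, 124 lower), 142 without SHAM replicate 2, 1183 without SHAM replicate 3 (432 higher, 751 lower), 113, 154 and 58 without DN replicates 1, 2 and 3, and 230 and 247 without DN-SM replicates 1 and 2. It was 156 in the fit of these 2 groups alone, 758 by DESeq2 (347 higher, 411 lower) and 275 by limma on log2 FPKM (202 higher, 73 lower). Ciart, Tmem158, Ltb, Bmal1, Fkbp5 and Aqp4 passed with each library left out in turn. The adjusted p reached 0.054 for Apod, 0.0586 for Cdkn1a, 0.08 for Ankrd1, 0.0705 for Thrsp and 0.169 for Chac1 without SHAM replicate 2. It reached 0.0877 for Cst7, 0.127 for Myh3, 0.0965 for Cib2, 0.0525 for Unc5a, 0.0616 for Dnajc21, 0.0853 for Myog and 0.0765 for Fbxo32 without DN replicate 3. These were their highest values, and calls were also lost without SHAM replicate 1 (Cst7, Thrsp, Fbxo32), SHAM replicate 2 (Cst7, Fbxo32), SHAM replicate 3 (Cst7, Myh3, Chac1), DN replicate 1 (Cst7, Myh3, Cib2, Chac1, Myog, Fbxo32), DN replicate 2 (Myh3, Thrsp, Cib2), DN replicate 3 (Ankrd1, Thrsp, Chac1), DN-SM replicates 1 and 2 (Myh3, Chac1) and DN-SM replicate 3 (Chac1). Calls were lost too without a filter (Cst7, Myh3, Chac1), with the replicate block (Cst7, Myh3), by voom with sample weights (Tmem158, Cst7), and by limma on log2 FPKM with a pseudocount of 0.1 (Fbxo32) or without a filter (Cst7, Thrsp, Chac1, Aqp4, Myog, Fbxo32).

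Among the gene lists in DN against SHAM, the denervation-responsive regulators rose: 5 of 13 members were higher over all genes and 9 adjusted over the list alone, with a median log2 fold change of 0.98 (camera adjusted p = 1.22e-08; adjusted p = 0.0537 with an estimated correlation, and 0.0245 without DN replicate 2). Mt1, a metal-binding metallothionein, was among them at 1.87 (adjusted p = 0.0122). The embryonic and neonatal sarcomere genes rose, with 3 of 7 higher and 4 adjusted over the list alone. The median was 0.94 (adjusted p = 2.49e-05; adjusted p = 0.108 with an estimated correlation). Myh3, the embryonic myosin heavy chain, was at 3.79 ± 2.38 FPKM in SHAM and 21.2 ± 7.75 in DN (log2 fold change 2.43, adjusted p = 0.0361), Actc1, the cardiac actin of developing muscle, rose by 1.78 (0.0441) and Tnnt2, the cardiac troponin T, by 1.34 (0.0396). The neuromuscular junction list rose, with 1 of 14 members higher, and also 1 adjusted over the list alone. The median was 0.18 (adjusted p = 0.00778; adjusted p = 0.338 with an estimated correlation). That member was Ncam1, an adhesion molecule of denervated fibres (1.07, adjusted p = 0.0281). The acetylcholine receptor subunits Chrna1, at 0.64 (adjusted p = 0.159), and Chrng, at 1.69 (0.18), did not pass. The junction list was not called without SHAM replicate 3 (adjusted p = 0.0799).

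Contractile and metabolic lists moved in DN against SHAM as well. Glycolysis and glycogen genes fell, with 3 of 22 lower and 7 adjusted over the list alone. The median was -0.38 (adjusted p = 1.09e-05; adjusted p = 0.358 with an estimated correlation). Hk2, the hexokinase of muscle, fell by 0.72 on the log2 scale (adjusted p = 0.0185), Pfkm, the muscle phosphofructokinase, by 0.67 (0.0443), and Phkg1, a subunit of phosphorylase kinase, by 0.94 (0.0458). Genes of excitation-contraction coupling fell, with 3 of 15 lower; adjusted over the list alone 6 were lower and 1 higher (median -0.35, adjusted p = 0.00441; adjusted p = 0.371 with an estimated correlation). They included the sodium channel Scn4a (-0.64, adjusted p = 0.00825), the potassium channel Kcnj11 (-0.85, 0.0114) and the calcium channel Cacna1s (-0.67, 0.0285). The fast-fibre list fell, with 1 of 17 lower and 3 adjusted over the list alone. The median was -0.39 (adjusted p = 0.0315; adjusted p = 0.6 with an estimated correlation). Its called member was Mylk2, the kinase of the myosin light chain (-1.16, adjusted p = 0.00882). The slow-fibre list rose with 0 of 13 members past the threshold, and also 0 adjusted over the list alone. Its median was 0.68 (adjusted p = 0.00629; adjusted p = 0.6 with an estimated correlation). The fast-fibre call was lost without SHAM replicate 2 (adjusted p = 0.127), SHAM replicate 3 (0.245) or DN replicate 3 (0.15), and the slow-fibre call without SHAM replicate 2 (0.0993). Oxidative phosphorylation genes were called as higher only without SHAM replicate 3 (0.0397) or DN replicate 1 (0.00865), and fatty acid oxidation genes without DN replicate 1 (0.0167). Neither was called with an estimated correlation.

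The myosin heavy chains showed the spread of SHAM. Myh4, the fastest adult isoform, made up 45.3% ± 26.1 of the FPKM summed over 6 myosin genes in SHAM (SD, n = 3), with a range from 26.9% to 75.2%, 15.9% ± 1.72 in DN and 29.0% ± 5.64 in DN-SM. Myh7, the slow isoform, made up 14.2% ± 9.16, 26.9% ± 5.95 and 15.2% ± 7.43. In DN against SHAM neither Myh4 (log2 fold change -2.11, adjusted p = 0.0625) nor Myh7 (0.62, adjusted p = 0.384) passed the test, and Myh4 passed when any 1 of the SHAM libraries was left out (lowest adjusted p = 0.0307 without SHAM replicate 1). Its log2 fold change was -2.48 without SHAM replicate 1 and -1.19 without SHAM replicate 2. How reads were divided among the related myosin genes was not tested.

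Lists of proteolysis, stress and proliferation also moved in DN against SHAM. The ubiquitin ligases of muscle atrophy fell, with 2 of 14 lower and 4 adjusted over the list alone. The median was -0.13 (adjusted p = 0.0132; adjusted p = 0.194 with an estimated correlation; 0.0581 at the preset correlation without SHAM replicate 3). The called members were Fbxo32 and Asb2, a ligase adaptor for filamins that fell from 600.0 ± 58.0 to 278 ± 54.2 FPKM (log2 fold change -1.20, adjusted p = 0.00348). Heat shock genes rose, with 1 of 14 higher (Hspb6, a small heat shock protein, 1.06, adjusted p = 0.0452); adjusted over the list alone 4 were higher and 1 lower (median 0.26, adjusted p = 0.0452; adjusted p = 0.6 with an estimated correlation). The heat shock call was lost without SHAM replicate 2 (0.127), SHAM replicate 3 (0.0581), DN replicate 3 (0.284) or DN-SM replicate 1 (0.0581). The proliferation list had a median of 0.87 (adjusted p = 0.0132; adjusted p = 0.338 with an estimated correlation), and was not called in the fit of DN and SHAM alone (adjusted p = 0.0823; adjusted p = 0.383 with an estimated correlation). Of its 12 members 0 were higher and 1 lower, and 5 were higher and 1 lower adjusted over the list alone; the lower one was Tpx2, a spindle assembly factor (-1.80, adjusted p = 0.0297). Interferon response genes rose with 0 of 18 members past the threshold, and also 0 adjusted over the list alone. The median was 0.57 (adjusted p = 0.00028; adjusted p = 0.338 with an estimated correlation).

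Markers of some other cell types were higher in DN than in SHAM, beside the muscle genes above. Schwann cell and nerve markers rose, with 3 of 11 higher and 10 adjusted over the list alone. The median was 1.06 (adjusted p = 1.22e-08; adjusted p = 0.194 with an estimated correlation). The 3 were Ngfr, a neurotrophin receptor of denervated Schwann cells (1.83, adjusted p = 0.0136), and the myelin genes Mbp (1.95, 0.0455) and Cnp (0.80, 0.0478). Endothelial markers rose, with 5 of 14 higher and 9 adjusted over the list alone. The median was 0.58 (adjusted p = 3.14e-06; adjusted p = 0.0537 with an estimated correlation). Pecam1, an endothelial adhesion molecule, was at 0.63 (adjusted p = 0.0123) and Cdh5, the cadherin of endothelial junctions, at 0.65 (0.0137). Adipocyte markers rose, with 2 of 9 higher and 3 adjusted over the list alone. The median was 0.75 (adjusted p = 0.000396; adjusted p = 0.338 with an estimated correlation). The 2 were Thrsp and the lipid droplet protein Cidea (2.05, adjusted p = 0.0361). Collagens and matrix genes rose, with 2 of 23 higher and 4 adjusted over the list alone. The median was 0.16 (adjusted p = 0.0132; adjusted p = 0.616 with an estimated correlation). The list was not called without SHAM replicate 2 (adjusted p = 0.981). Col4a1, a basement membrane collagen, was at 1.07 (adjusted p = 0.00823), and Col1a1, the main fibrillar collagen, at -0.21 (0.765; from -0.55 to 0.18 with 1 library left out).

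Of the 47 list members called in DN against SHAM, 6 stayed called with each library left out (Asb2, Bmal1, Ciart, Col4a1, Mylk2 and Per2). The number lost was 15, 27 and 8 without SHAM replicates 1, 2 and 3, 28, 22 and 39 without DN replicates 1, 2 and 3, and 15, 15 and 7 without DN-SM replicates 1, 2 and 3. In the fit of DN and SHAM alone the members no longer called included all 3 embryonic sarcomere genes (Myh3, Actc1 and Tnnt2), Fbxo32, Ncam1, Cacna1s, Pfkm, Phkg1, Hspb6, Npas2, Chac1, Igf2 and Cd34.

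The comparison of DN-SM with DN addressed what electrical stimulation did to the injured muscle. In the fit of all 9 libraries 1 gene of 10129 passed the test, Serpina3n, a secreted serine protease inhibitor (gene ID 24795). It was at 4.76 ± 0.893 FPKM in DN, 0.333 ± 0.25 in DN-SM and 0.30 ± 0.19 in SHAM (SD, n = 3; DN-SM against DN log2 fold change -3.73, SE 0.453, edgeR adjusted p = 0.022; DN against SHAM 3.87, adjusted p = 0.00235). Its level lies below the floor of the naming rule, so it was chosen after its values were seen. An unadjusted p under 0.05 was found for 1784 genes. DESeq2 called 215 (169 higher, 46 lower) without Serpina3n among them, voom with sample weights 515, and the edgeR fit of DN and DN-SM alone 716 (592 higher, 124 lower).

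The 4 genes with the smallest p that met the FPKM floor in DN-SM against DN did not pass, each with an adjusted p of 0.144. They were Aqp4 (1.58; 2.24 ± 0.335 FPKM in DN, 6.38 ± 1.14 in DN-SM and 7.16 ± 2.77 in SHAM), Slc22a17, a receptor for lipocalin 2 (-0.85), Synm, an intermediate filament protein of the Z-disc (0.80), and Septin7, a cytoskeletal GTPase (1.08). Without SHAM replicate 2 or 3 all 4 passed, with Aqp4 at 0.0038 without SHAM replicate 3. None of the denervation and fibre genes followed in every comparison passed in the fit of all 9 libraries. Chrna1 was at -0.49 (adjusted p = 0.324), Chrng at -1.15 (0.371) and Myog at -0.40 (0.232). With 1 library left out Chrng ranged from -2.39 to -0.69. Fbxo32 was at -0.29 (0.647), Trim63 at -0.01 (0.987; from -0.13 to 0.08 with 1 library left out), Myh7 at -0.35 (0.663) and Ppargc1a, a coactivator of mitochondrial genes, at 0.61 (0.29). Myh4 was at 926 ± 92.3 FPKM in DN and 2253 ± 568 in DN-SM (1.37, adjusted p = 0.233; 0.011 without SHAM replicate 2), and Col1a1 at 261 ± 46.9 and 148 ± 35.7 FPKM (-0.72, 0.31).

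**Figure D2:**
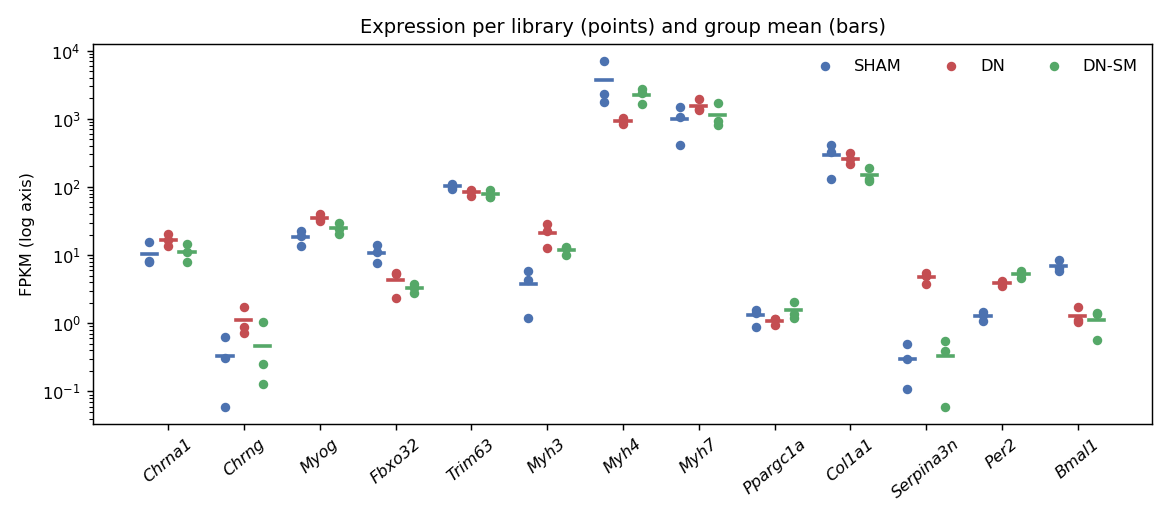
FPKM (log axis) of 13 genes in each library (points) with the group mean (bars), for SHAM, DN and DN-SM, 3 libraries each. Serpina3n had a mean of 4.76 FPKM in DN and 0.333 in DN-SM, and Bmal1 6.94 in SHAM and 1.29 in DN.

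The edgeR fit of the DN and DN-SM libraries alone was an alternative planned with the others. In it the largest rises in DN-SM against DN included Aqp4 (1.59, adjusted p = 0.00083) and Gpcpd1, a phosphodiesterase of phospholipid breakdown (1.42, 0.00479). They also included Myh4 (1.38, 0.0035) and Capza2, an actin-capping protein (1.31, 0.00083). The largest falls included G0s2, an inhibitor of fat breakdown (-1.30, 0.00816), Ccl21, a chemokine (-1.14, 0.00673), S100a4, a calcium-binding protein of fibroblasts and leukocytes (-0.97, 0.0204), and Junb, an immediate early transcription factor (-0.95, 0.0118). The naming rule was applied to this fit after the data were seen. For these genes the SHAM libraries varied too. The median of the 592 higher genes minus that of the 124 lower ones, centred, was 0.207, 0.985 and -0.469 in SHAM replicates 1, 2 and 3. It was -0.817 to -0.701 in DN and 0.492 to 0.591 in DN-SM. The genes were picked for their difference between these DN and DN-SM libraries, so the separation and narrow ranges of those groups follow from the pick.

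Whole lists moved between DN-SM and DN, with 0 members past the threshold over all genes in each of them in the fit of all 9 libraries. Those lower in DN-SM included the immediate early genes (0 of 13, and 6 lower adjusted over the list alone; median -0.49, camera adjusted p = 0.000156; adjusted p = 0.427 with an estimated correlation), with Fosb at -1.32 and Junb at -0.96 (both adjusted p = 0.144). Junb was higher in DN than in SHAM (0.86, adjusted p = 0.036). Collagens and matrix genes (0 of 23, and 0 adjusted over the list alone) had a median of -0.43 (adjusted p = 0.000227; adjusted p = 0.594 with an estimated correlation). Tendon markers (0 of 8, and 3 lower adjusted over the list alone) had a median of -0.83 (adjusted p = 0.000597; adjusted p = 0.594 with an estimated correlation), with the tendon matrix protein Comp at -1.95 (0.144). Embryonic sarcomere genes (0 of 7, and 2 lower adjusted over the list alone) had a median of -0.65 (adjusted p = 0.00201; adjusted p = 0.426 with an estimated correlation), with Actc1 at 171 ± 80.2 FPKM in DN and 51.8 ± 11.3 in DN-SM (-1.62, adjusted p = 0.144). Schwann cell markers (0 of 11, and 0 adjusted over the list alone) had a median of -0.76 (adjusted p = 0.000669; adjusted p = 0.594 with an estimated correlation).

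Other lists were lower in DN-SM than in DN as well. They were the interferon response (0 of 18, and 0 adjusted over the list alone; median -0.29, adjusted p = 0.00239; adjusted p = 0.594 with an estimated correlation) and adipocyte markers (0 of 9, and 2 lower adjusted over the list alone; -0.73, 0.00584; adjusted p = 0.594 with an estimated correlation). Endothelial markers (0 of 14, and 0 adjusted over the list alone; -0.24, 0.00916; adjusted p = 0.426 with an estimated correlation) and slow-fibre genes (0 of 13, and 0 adjusted over the list alone; -0.36, 0.0271; adjusted p = 0.675 with an estimated correlation) were lower too. Fast-fibre genes were higher in DN-SM (0 of 17, and 0 adjusted over the list alone; 0.32, 0.00183; adjusted p = 0.594 with an estimated correlation). So were glycolysis genes (0 of 22, and 0 adjusted over the list alone; 0.26, 0.00183; adjusted p = 0.594 with an estimated correlation). Genes of the tricarboxylic acid cycle were higher too (0 of 20, and 6 adjusted over the list alone; 0.15, 0.00472; adjusted p = 0.531 with an estimated correlation), with the fumarase gene Fh at 0.48 and the pyruvate dehydrogenase gene Pdha1 at 0.80 (both 0.144).

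In the fit of DN and DN-SM alone these lists were called as well, and more of their members passed over all genes. Lower were 6 collagens and matrix genes (12 adjusted over the list alone), 4 tendon markers (5), 3 immediate early genes (4), 1 embryonic sarcomere gene (2) and 1 endothelial marker (2). Higher were 6 genes of the tricarboxylic acid cycle (6), 4 fast-fibre genes (9, with 1 lower) and 1 glycolysis gene (1). For Schwann cell, adipocyte, interferon and slow-fibre genes both counts were 0. Heat shock genes were also called as lower in this fit (adjusted p = 0.0355; adjusted p = 0.609 with an estimated correlation), with 0 members past the threshold. With an estimated correlation 0 lists were called in this fit.

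In DN-SM against DN the number of called genes was 339 without SHAM replicate 2 and 416 without SHAM replicate 3, 2 without DN-SM replicate 1, and 0 without any other library. The common dispersion of counts, as a coefficient of variation, was 0.219 within SHAM, 0.143 within DN and 0.142 within DN-SM. Of the moved lists, slow-fibre genes were no longer called without SHAM replicate 3 (0.0665), DN replicate 3 (0.134), DN-SM replicate 1 (0.172) or 2 (0.205). Neither were adipocyte markers without DN replicate 2 (0.0763) or DN-SM replicate 1 (0.118), interferon genes without DN replicate 2 (0.0639), nor glycolysis genes and endothelial markers without DN replicate 3 (both 0.0568). Other lists were called as lower when 1 library was left out, but not in the fit of all 9. They were the neuromuscular junction list without SHAM replicate 1 (0.0425), DN replicate 2 (0.0161) or DN-SM replicate 3 (0.00206), and the denervation-responsive regulators without DN replicate 2 (0.0168). Heat shock genes were called without SHAM replicate 2 (0.0205), DN replicate 1 (0.0108) or DN-SM replicate 3 (0.00593), and proliferation genes without SHAM replicate 1 (0.0482), DN replicate 1 (0.0173) or DN-SM replicate 2 (0.0158). Genes of excitation-contraction coupling were called as higher without SHAM replicate 2 (0.0323) or DN replicate 1 (0.00449). None of these calls held with an estimated correlation.

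**Figure D3:**
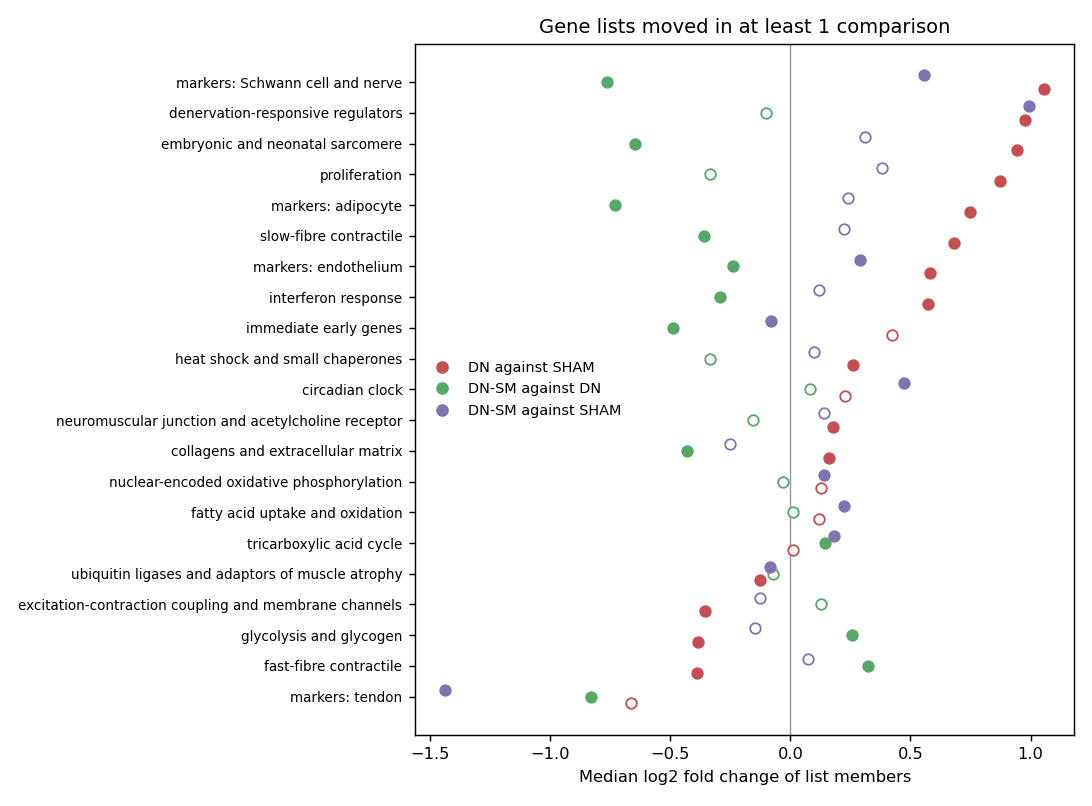
Median log2 fold change (horizontal axis) of the members of each gene list that moved in at least 1 comparison, for DN against SHAM, DN-SM against DN and DN-SM against SHAM; filled points had a camera adjusted p under 0.05 at the preset correlation, open points did not. Schwann cell and nerve markers had medians of 1.06, -0.76 and 0.56, and no call held with an estimated correlation.

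The comparison of DN-SM with SHAM addressed how far the stimulated muscle stayed from the sham-operated one. Genes of the circadian clock were among those that differed. Per2, a repressor of the clock, rose from 1.29 ± 0.186 to 5.26 ± 0.636 FPKM (gene ID 63840; SD, n = 3; log2 fold change 2.05, SE 0.153, edgeR adjusted p = 8.89e-05), and Ciart rose by 3.46 (0.0123). Dbp, a transcription factor driven by the clock, rose from 45.8 ± 17.4 to 193 ± 28.8 FPKM (2.13, 0.0291), and Bmal1 had a log2 fold change of -2.59 (0.00144). Cdkn1a (2.48, 0.0349) and Ankrd1 (2.37, 0.0299) were higher in DN-SM than in SHAM, as was Gadd45a, a stress-induced gene of denervated muscle (1.64, 0.0214). Fbxo32 was lower at 3.29 ± 0.482 FPKM (-1.69, 0.029), as was Ucp3, a mitochondrial uncoupling protein (44.4 ± 16.8 and 9.49 ± 4.09 FPKM; -2.22, 0.039).

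Of 10129 genes tested in DN-SM against SHAM, 85 changed, 42 higher and 43 lower in DN-SM. The change was at least 2-fold in 45 of them, and 1293 genes had an unadjusted p under 0.05. Of the 69 genes that met the naming rule, the remaining large rises were in Tmem158 (2.52, adjusted p = 0.0224) and Apod (2.50, 0.0455). The remaining large falls were in Chad, a cartilage and tendon matrix protein (-2.83, 0.0349), and Fos, an immediate early transcription factor (-2.18, 0.0498). They were also in Spon2, a secreted matrix protein (-1.96, 0.0184), Ltb (-1.69, 0.0123) and Fcgr2al1, an immunoglobulin receptor gene (-1.59, 0.0304). Chrna1 (0.16, adjusted p = 0.846), Chrng (0.54, 0.827), Myog (0.46, 0.25), Trim63 (-0.37, 0.313), Myh4 (-0.74, 0.595), Myh7 (0.27, 0.819), Ppargc1a (0.28, 0.719) and Col1a1 (-0.94, 0.294; 0.0169 without SHAM replicate 2) did not pass. With 1 library left out the direction turned for Chrna1 (-0.09 to 0.44), Chrng (-0.71 to 1.22), Myh4 (-1.11 to 0.19) and Myh7 (-0.12 to 0.59).

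In DN-SM against SHAM the count was 34 without SHAM replicate 1, 137 without SHAM replicate 2, 35 without SHAM replicate 3, 36 and 39 without DN replicates 1 and 2, and 15, 22 and 18 without DN-SM replicates 1, 2 and 3. It was 28 in the fit of these 2 groups, 39 with the replicate number as a block, 259 by DESeq2 and 42 by limma on log2 FPKM. Ciart, Per2 and Bmal1 passed with each library left out. The adjusted p reached 0.0792 for Tmem158, Ankrd1 and Gadd45a and 0.121 for Fcgr2al1 without DN-SM replicate 2, 0.176 for Apod and 0.119 for Cdkn1a without SHAM replicate 3, and 0.0774 for Dbp, 0.116 for Chad and 0.0786 for Spon2 without DN-SM replicate 3. It was 0.16 for Ucp3, 0.194 for Fos, 0.073 for Ltb and 0.119 for Fbxo32 without DN-SM replicate 1. These were their highest values, and calls were also lost without SHAM replicate 1 (Tmem158, Apod, Cdkn1a, Ankrd1, Gadd45a, Chad, Fos, Fbxo32, Fcgr2al1), SHAM replicate 2 (Apod, Cdkn1a, Ankrd1, Ucp3, Fos), SHAM replicate 3 (Tmem158, Dbp, Gadd45a, Chad, Ucp3, Fcgr2al1), DN replicate 1 (Apod, Cdkn1a, Ankrd1, Dbp, Chad, Ucp3, Fos, Fcgr2al1), DN replicate 2 (Chad, Ucp3, Fos, Fcgr2al1), DN replicate 3 (Apod, Ucp3, Fos), DN-SM replicate 1 (Tmem158, Apod, Cdkn1a, Dbp, Chad, Spon2, Fcgr2al1), DN-SM replicate 2 (Cdkn1a, Dbp, Chad, Fos, Spon2, Fbxo32) and DN-SM replicate 3 (Tmem158, Apod, Cdkn1a, Ankrd1, Gadd45a, Ucp3, Fos, Ltb, Fbxo32, Fcgr2al1). Calls were lost too with upper-quartile factors (Fos), without a filter (Apod, Cdkn1a, Ankrd1, Dbp, Ucp3, Fos), with the replicate block (Apod, Chad, Ucp3, Fos, Fbxo32), by voom with sample weights (Tmem158, Apod) and by limma on log2 FPKM with either pseudocount (Fos, Fbxo32, Fcgr2al1). By limma without a filter, Tmem158, Apod, Cdkn1a, Ankrd1, Gadd45a, Chad, Ucp3, Fos, Spon2, Ltb, Fbxo32 and Fcgr2al1 were not called.

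The denervation-responsive regulators rose in DN-SM against SHAM, with 3 of 13 members higher and 7 adjusted over the list alone. The median was 0.99 (camera adjusted p = 3.08e-08; adjusted p = 0.102 with an estimated correlation, and 0.0357 without DN replicate 2). The ubiquitin ligases fell, with 2 of 14 lower and 4 adjusted over the list alone. The median was -0.08 (adjusted p = 0.00116; adjusted p = 0.102 with an estimated correlation). The 2 were Fbxo32 and Asb2 (219 ± 23.9 FPKM; -1.44, adjusted p = 0.00144). The clock list was called as higher, with 3 of 14 members higher and 2 lower, and 8 higher and 4 lower adjusted over the list alone. The median was 0.47 (adjusted p = 0.00426; adjusted p = 0.171 with an estimated correlation). In DN against SHAM the same list also had 3 higher and 2 lower, and 7 higher and 4 lower adjusted over the list alone. The median was 0.23 (adjusted p = 0.0781), and the list was called there without SHAM replicate 2 (0.0397), DN replicate 3 (0.0265) or DN-SM replicate 3 (0.0378). Per2 rose by 1.52 in that comparison (adjusted p = 0.00232) and Dbp by 2.12 (0.0136).

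Mitochondrial lists were higher in DN-SM than in SHAM. They were oxidative phosphorylation (0 of 40 members called, and 0 adjusted over the list alone; median 0.14, adjusted p = 0.00499; adjusted p = 0.712 with an estimated correlation) and the tricarboxylic acid cycle (0 higher and 1 lower of 20, and 2 higher and 1 lower adjusted over the list alone; 0.18, 0.0316; adjusted p = 0.468 with an estimated correlation). Fatty acid oxidation was higher as well (0 higher and 1 lower of 23, and 1 higher and 1 lower adjusted over the list alone; 0.23, 0.0413; adjusted p = 0.721 with an estimated correlation). The called members went the other way: Pdk4, the kinase that inhibits pyruvate dehydrogenase (-1.11, adjusted p = 0.0414), and Ucp3. None of these calls held without SHAM replicate 2 (0.218, 0.138 and 0.555) or without DN-SM replicate 3 (0.0876, 0.113 and 0.769), nor did that of the tricarboxylic acid cycle without DN-SM replicate 2 (0.0606).

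Tendon markers fell in DN-SM against SHAM, with 2 of 8 lower (Chad, and Comp at -2.49, adjusted p = 0.0414) and 6 adjusted over the list alone. The median was -1.44 (adjusted p = 3.69e-08; adjusted p = 0.381 with an estimated correlation). In DN against SHAM their median was -0.66 (adjusted p = 0.171; 0.00223 without SHAM replicate 2). Collagens and matrix genes had a median of -0.25 in DN-SM against SHAM (adjusted p = 0.331; 4.63e-07 without SHAM replicate 2). The immediate early genes fell, with 2 of 13 lower, and also 2 adjusted over the list alone. The median was -0.08 (mean -0.41, adjusted p = 0.02; adjusted p = 0.468 with an estimated correlation). The 2 were Fos and Fosb (-2.25, adjusted p = 0.00762); the list was not called without SHAM replicate 1 (0.139), DN-SM replicate 1 (0.282) or DN-SM replicate 2 (0.0624). Schwann cell markers stayed higher (0 of 11 past the threshold, and 2 higher adjusted over the list alone; 0.56, 0.00426; adjusted p = 0.468 with an estimated correlation). So did endothelial markers (1 of 14, and 4 higher and 1 lower adjusted over the list alone; 0.29, 0.00867; adjusted p = 0.171 with an estimated correlation), with Cdh5 at 0.59 (0.0448). Without SHAM replicate 2 the adjusted p was 0.063 for Schwann cell and 0.0882 for endothelial markers, and without DN-SM replicate 3 it was 0.277 for Schwann cell markers. Glycolysis genes were called as lower only without SHAM replicate 1 (0.000381) or DN-SM replicate 1 (0.0274). Slow-fibre genes were called as higher only without SHAM replicate 1 (0.0122), adipocyte markers without DN-SM replicate 1 (0.0101), and proliferation genes without DN-SM replicate 3 (0.0281). None of these calls held with an estimated correlation.

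Of the 23 list members called in DN-SM against SHAM, 5 stayed called with each library left out (Asb2, Bmal1, Ciart, Fosb and Per2). The number lost was 14, 7 and 14 without SHAM replicates 1, 2 and 3, 11, 9 and 5 without DN replicates 1, 2 and 3, and 16, 15 and 16 without DN-SM replicates 1, 2 and 3. In the fit of DN-SM and SHAM alone the members no longer called included both tendon markers (Chad and Comp), Ankrd1, Dbp, Npas2, Fos, Ucp3, Pdk4, Cdh5, Tpx2 and Ulk1, and of the other genes named above Apod, Spon2 and Fcgr2al1 were not called.

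The position of the stimulated muscle between SHAM and DN was read from the 432 genes changed in DN against SHAM. Of these, 62 were also called in DN-SM against SHAM in the same direction and 0 in the opposite direction. Independent lists would share 1.81. Simulated data with no difference between groups shared 0.1 on average, but only 0.5 and 0.3 genes were called there, so this overlap could not be large. Since both comparisons use the SHAM libraries, part of the excess may come from the shared controls. Across all genes the 2 sets of fold changes had a correlation of 0.568 and a covariance of 0.102, and the simulated data with no difference had 0.503 and 0.0479. The simulation gave every group the pooled dispersion of each gene. As a coefficient of variation, the common dispersion of the pooled fit was 0.171, while that within SHAM was 0.219. The simulated values thus likely understate what shared SHAM libraries give, and how much of the excess they explain stays open. Genes are not independent replicates.

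Over those 432 genes, the slope of the DN-SM against SHAM change on the DN against SHAM change was 0.626, with a range of 0.546 (without SHAM replicate 3) to 0.704 (without DN replicate 3) when each library was left out. In simulated data with DN-SM equal to DN the slope was 0.882 (SD 0.0149), over more genes (1259 called on average). Those data were drawn from the fitted means, which already hold the noise of these libraries, so their DN against SHAM changes were too large. Their slope and signs are therefore no like baseline, and the gap to 0.626 cannot show that stimulation moved these genes back. In DN-SM against DN, 391 of the 432 (90.5%) had a sign opposite to their change in DN against SHAM, compared with 67.4% in those simulated data. Only Serpina3n passed the test in both comparisons with opposite signs, and 0 genes passed with the same sign. Independent lists would give 0.03. The simulated data gave 0.05 on average, with only 0.5 genes called in DN-SM against DN. The count of genes that moved back in this sense was 105 by DESeq2, 33 in the fits of 2 groups and 122 by voom with sample weights. It was 25 without SHAM replicate 2 and 321 without SHAM replicate 3, 2 without DN-SM replicate 1, and 0 without any other library. The DN libraries are shared here. Across all genes the correlation of the 2 sets of changes was -0.627 with a covariance of -0.1189, and -0.493 with -0.0466 in simulated data with no difference between groups. The simulation gave DN the pooled dispersion of each gene, and the common dispersion of the pooled fit was above that within DN. These simulated values thus likely overstate in size what shared DN libraries give.

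**Figure D4:**
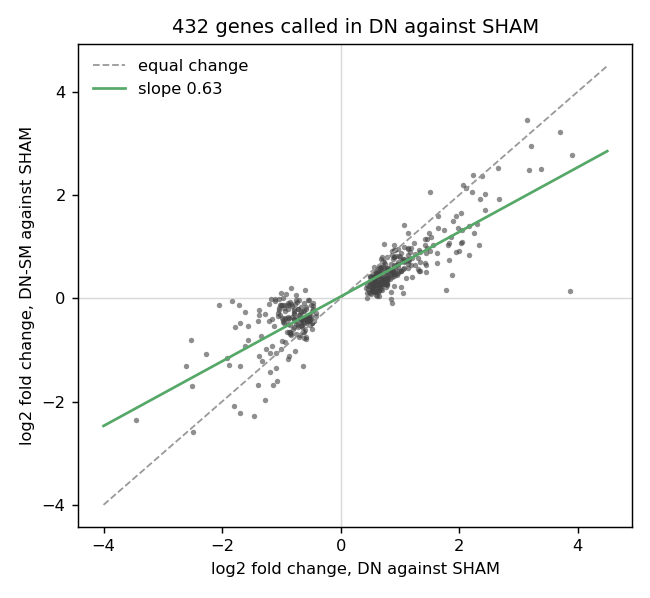
Log2 fold change in DN against SHAM (horizontal) and in DN-SM against SHAM (vertical) of the 432 genes called in DN against SHAM, 1 point per gene. The dashed line marks equal change, and the solid line has the fitted slope of 0.626; both axes share the SHAM libraries.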

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

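The fit of DN and DN-SM alone was planned, while its own variants, the list tests in fits of 2 groups and those with an estimated correlation and a library left out were chosen after the data were seen. With each library left out in turn the counts of changed genes ranged from 58 to 1183 in DN against SHAM, 0 to 416 in DN-SM against DN and 15 to 137 in DN-SM against SHAM. Genes moved back ranged from 0 to 321, and lists moved from 12 to 18, 9 to 16 and 8 to 11 in the same order. The slope of the DN-SM against SHAM change on the DN against SHAM change ranged from 0.546 to 0.704. It was 0.882 in simulated data with DN-SM equal to DN, whose DN against SHAM changes were too large for a like comparison. Counts stayed within 1.5 times under RLE and upper-quartile factors, no filter, the CPM filter and library sizes without the 20 most abundant genes. In the order of DN against SHAM, DN-SM against DN and DN-SM against SHAM, DESeq2 gave 758, 215 and 259, the fits of 2 groups 156, 716 and 28, limma on log2(FPKM + 1) 275, 1 and 42, with a pseudocount of 0.1 243, 0 and 43, and without a filter 112, 1 and 12; with 0 calls by limma, 1747 genes had an unadjusted p under 0.05. Sample weights gave 515 in DN-SM against DN, and the replicate block 39 in DN-SM against SHAM. DESeq2 called 407 of the 432 genes of DN against SHAM, the fit of 2 groups 149, and limma on log2(FPKM + 1) 245. Genes moved back numbered 105 by DESeq2, 33 in fits of 2 groups, 122 with sample weights and 0 at a pseudocount of 0.1, and that slope was 0.563 by DESeq2 and 0.561 with sample weights. With an estimated correlation 0 lists moved in each comparison, and with each library left out 0 moved except the denervation-responsive regulators without DN replicate 2, in DN against SHAM (adjusted p = 0.0245) and DN-SM against SHAM (0.0357). In the same order fry gave 5, 0 and 5. The fit of DN and DN-SM alone gave 235 with limma on log2(FPKM + 1), 691 with RLE factors, 616 by DESeq2, 818 with the block and 674 with the length correction; with each library left out it ranged from 274 (without DN-SM replicate 2) to 537. The causes weighed for DN-SM against DN were the wider spread of SHAM, transcript length and sample make-up. For the clock genes they were collection time and sample make-up, and for Fbxo32, Pdk4 and Ucp3 a glucocorticoid or fasting signal. Splits of the libraries were run as well, and other causes were not tested.

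Over the alternatives to the list tests, 1238 of 1386 results kept their side of the threshold, 100 were lost, 48 were gained and 0 reversed a call. For named genes these were 1100, 165, 30 and 0 of 1295. Both totals include lists and genes not called in the main fit, which had no call to lose. Of 33 lists the main fit called 15 in DN against SHAM, 12 in DN-SM against DN and 10 in DN-SM against SHAM. None of these held with an estimated correlation. The median of all genes moved furthest with limma at a pseudocount of 0.1, from -0.011 to -0.109 in DN-SM against DN. Residual correlations gave no clear sign that the numbers pair the samples. They ran from -0.048 to 0.109 for libraries with the same number in different groups, and from -0.097 to 0.066 for other pairs. The highest, 0.109, was that of DN and DN-SM replicate 3, above the threshold of 0.1 for this check. Of 9 libraries, 0 correlated best with their own number in both other groups. With 3 libraries per group, this check cannot exclude that a number marks a shared day or animal. Without 1 library, a group of 2 is assumed to vary like the others in the pooled fit. At this depth and number of libraries, the simulated test recovered 11 of 50 genes changed 1.5-fold in DN-SM against DN.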

Other observations

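Several gene groups written down for denervated muscle were not moved in any of the comparisons of all 9 libraries, listed here in the order DN against SHAM, DN-SM against DN and DN-SM against SHAM with camera adjusted p. They were the proteasome subunits (median log2 fold change -0.04, 0.09 and 0.04; 0.345, 0.218 and 0.815), autophagy and lysosome genes (-0.13, -0.02 and -0.06; 0.171, 0.777 and 0.0612), regulators of mitochondrial biogenesis (-0.27, 0.09 and 0.02; 0.102, 0.486 and 0.297) and myogenic progenitors (0.23, -0.25 and 0.01; 0.102, 0.101 and 0.815). Others were polyamine metabolism (-0.13, 0.16 and 0.07; 0.45, 0.548 and 0.815), the unfolded protein and stress response (0.09, 0.03 and -0.14; 0.551, 0.838 and 0.331) and growth factor, myostatin and FoxO signalling (-0.30, 0.07 and -0.26; 0.0609, 0.528 and 0.139). Some members passed in edgeR. Foxo4, an atrophy-related transcription factor, fell in DN against SHAM (-0.78, adjusted p = 0.0211). Igf2, a fetal growth factor, rose in DN (0.74, 0.0452) and in DN-SM (1.06, 0.0291) against SHAM, and Ulk1, the kinase that starts autophagy, fell in DN-SM against SHAM (-0.63, 0.0214). Some were called without 1 library. In DN against SHAM these were the proteasome (0.0451 without SHAM replicate 1), biogenesis (0.0293 without SHAM replicate 2) and growth factor lists (0.0447 without DN replicate 3), all lower. In DN-SM the progenitor list was lower than in DN (0.0403) and the autophagy list lower than in SHAM (0.00824), both without DN-SM replicate 3. None of these calls held with an estimated correlation. The median differed in sign from the mean or the test for autophagy in DN-SM against DN, for biogenesis and polyamine genes in DN-SM against SHAM, and for the stress response in DN against SHAM and in DN-SM against DN.

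Markers of immune cells were not called with all 9 libraries. Macrophage markers had medians of 0.04, -0.14 and -0.07 (adjusted p = 0.57, 0.274 and 0.551), and neutrophil and mast cell markers -0.36, -0.07 and -0.35 (0.254, 0.838 and 0.139). Medians were 0.00, -0.12 and -0.11 for fibroblasts and their progenitors (0.744, 0.486 and 0.61), 0.17, -0.21 and -0.01 for smooth muscle (0.57, 0.0883 and 0.261) and -0.57, 0.25 and -0.40 for red blood cells (0.131, 0.855 and 0.0612). For smooth muscle in DN against SHAM, and for neutrophil and red cell markers in DN-SM against DN, the mean or the test had the opposite sign to the median. Without 1 library, several of these were called as lower. In DN-SM against SHAM, macrophage (0.0412), fibroblast (0.0185) and smooth muscle markers (0.0127) were called without SHAM replicate 2. In DN-SM against DN, macrophage markers were called without DN replicate 1 (0.0108), and smooth muscle markers without SHAM replicate 2 (0.0482) or DN-SM replicate 3 (0.0141). Red blood cell markers were called in DN against SHAM without DN replicate 1 (0.00563) or DN-SM replicate 2 (0.0326), in DN-SM against SHAM without the same libraries (0.0391 and 7.01e-07), and in DN-SM against DN without DN-SM replicate 2 (0.0181). They were also called in the fits of 2 groups for DN against SHAM (0.0214; 0.487 with an estimated correlation) and DN-SM against SHAM (0.04; 0.726). With an estimated correlation none of the marker calls with 1 library left out held. Lists with too few members to test were lymphocytes (3 members; medians -0.14, -0.50 and -0.67) and the muscle spindle and motor axon (4 members; 0.44, -0.06 and 0.37). Cd34, a marker of progenitors that endothelium also expresses, rose in DN against SHAM (0.72, adjusted p = 0.0285). The myosin gene Myh1 made up 33.8% ± 14.0 of the summed myosin FPKM in SHAM, 46.2% ± 9.53 in DN and 49.9% ± 3.34 in DN-SM (SD, n = 3). Myh2 made up 6.66% ± 4.95, 10.6% ± 5.41 and 5.68% ± 1.29, and ranged from 2.28% to 12.0% in SHAM.

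Tests chosen after the data were seen were those of the spread of SHAM, of transcript length, of sample make-up, of the clock genes and of the glucocorticoid genes, and the splits of the fit of DN and DN-SM alone. The bounds of the length and glucocorticoid tests were written before the values they measure were seen. Of the 10 splits of the 6 libraries of each comparison into 3 and 3, only 1 split, the real one, gave as many changed genes: 432 in DN against SHAM with 1 as the highest of the others, 1 in DN-SM against DN with 0, 85 in DN-SM against SHAM with 7, and 716 in the fit of DN and DN-SM alone with 1. With 10 splits the share cannot fall under 0.1.

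DN-SM and DN gave different counts in different fits: they differed in 1 gene in the fit of all libraries and in 716 without the SHAM libraries. The common dispersion of the first fit was 1.45 times that of the second, so a wider spread in SHAM is a candidate explanation for the difference between these counts. Bias with transcript length is argued against as the whole cause of the 716 calls, since 578 of them stayed called when each library's length trend was removed. The total was then 674 (94.1%), with 473 higher instead of 592 and 201 lower instead of 124. The higher genes had a median length of 2773.5 bases, compared with 2154 in genes not called, so a part of the calls may reflect length. The score of these genes, which were picked for their difference between DN-SM and DN, ranged among the 3 SHAM libraries over 112.3% of that difference. SHAM replicate 2 had the highest score (0.985) and the highest Myh4 share, 75.2%, but the other SHAM libraries did not follow this order. Replicate 3 had the lowest score (-0.469) at a share of 33.8%, and replicate 1 a score of 0.207 at 26.9%. Myh4 was also among the genes picked as higher, so the match in replicate 2 was partly built in. Given the range among the SHAM libraries, sample make-up or RNA quality that varies without stimulation stays open. An effect of stimulation, the difference that the design names, stays open beside it. The labels do not state when DN muscle was collected, so a difference in collection time cannot be told apart from that effect.

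The clock genes differed from SHAM in both injured groups. In DN and in DN-SM against SHAM, 5 of 14 were called: Bmal1 and Npas2 were lower, and Per2, Ciart and Dbp higher. Nr1d1, of the Per2 arm, had log2 fold changes of -0.12 and -0.58 (adjusted p = 0.753 and 0.203). The median of the Per2 arm lay 2.23 log2 units above that of the Bmal1 arm in DN against SHAM (1.00 and -1.23) and 2.86 in DN-SM against SHAM (1.14 and -1.72). Fewer fibres and more cells of other types were taken to move both arms the same way, unlike the gap of 2.86. The arms hold the clock genes already seen to move in opposite directions, so this test could not have come out otherwise. Whether the cell types of the tissue hold both arms in the same ratio was not tested, so sample make-up stays open here. Collection of SHAM tissue at another time of day predicts such opposite shifts, but so may an effect of nerve injury on the clock; since no collection time is given, these cannot be told apart.

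Fbxo32, Pdk4 and Ucp3 were lower in both injured groups than in SHAM. A lower glucocorticoid or fasting signal at collection is a candidate explanation that predicts lower levels of 12 further genes of that response, picked without looking at their values. Their medians were -0.14 in DN and 0.30 in DN-SM against SHAM, with 9 and 3 of 12 negative. Lpin1, a regulator of fat metabolism, was the only one called (-0.77, adjusted p = 0.028, and -1.03, adjusted p = 0.0184). Fkbp5, the co-chaperone of steroid receptors among the largest falls in DN against SHAM, was not among the 12. It was lower in DN (-1.78, edgeR adjusted p = 0.00235), at 5.31 ± 0.737 FPKM in SHAM, 1.63 ± 0.341 in DN and 3.58 ± 0.781 in DN-SM. The value of 0.30 met the bound of 0 set against this explanation, but the medians with each library left out ranged from -0.02 to 0.41, and that the bound had to be exceeded by more than this range was applied after the value was seen. It thus stays open, as does an effect of nerve injury, which was not tested separately.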
